A study of Mus musculus with 4 samples.

How the data were processed

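Single-cell RNA sequencing (10x Genomics Chromium) was performed on Lin-Sca1-Kit+CD34+ progenitors of mouse fetal liver at E14.5, from 2 wild-type and 2 enhancer-deleted embryos. Per the labels, the submitters used Cell Ranger 2.0.2, Seurat 2.3.4 and the mm10 genome. The deposited table holds counts, as whole-number UMIs (unique molecular identifiers) of 3624 genes in 9960 cells, with no normalization. The other deposited files hold gene symbols, and the genotype and library letter of each cell, which are neither counts nor another measured unit. The cells were subsampled to 4980 per genotype before deposition. How the submitters chose genes and cells is not stated, and 99 genes had a UMI in under 10% of cells, the rarest in 11 cells. Levels are therefore given as CPM of the panel, the UMIs of a gene scaled to the library's total of panel UMIs, and a gene outside the panel was not measured. The table has no header, and its cells were taken in the order of the grouping file. The letters F and I stand for the wild-type libraries and A and B for the enhancer-deleted ones.

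UMIs were summed over all cells of a library, so that the library was the unit of replication. Counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The median gene moved by 0.00 on the log2 scale. Positive log2 fold changes are higher in the enhancer-deleted libraries, and SE is the standard error of the fitted log2 fold change. Levels are given as the mean and SD of 2 libraries. Gene symbols were matched to GENCODE release M21, and 3522 of 3624 had a single gene there.

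Genes were named by a rule fixed before the data were examined. It took Gata2, and for all cells the 10 largest rises and 10 largest falls past the threshold, with both libraries of a genotype above both of the other and at least 20 CPM in the higher group. It also took up to 3 members with the smallest p of each gene list, and 5 rises and 5 falls within each cell class. The gene lists, also fixed before, were HSPC/multipotent, erythroid, megakaryocyte, basophil/mast, eosinophil, neutrophil, monocyte/macrophage, dendritic, B lymphoid, T/NK/ILC, hepatoblast, endothelial, stromal and mature liver macrophage markers, hematopoietic transcription regulators, interferon response, innate immune receptors and signalling, S phase, G2/M phase, heme synthesis, ribosomal protein, immediate early and dissociation, sex-linked genes and growth factor receptors. Lists with 3 or more measured genes were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), with an estimated correlation and fry beside it. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment within the list, and take genes of either direction.

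Cells were scaled to 10000 counts, and 1000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1.0 (scanpy 1.11.5, python-igraph 0.11.9). A cluster was named for a list when at least 3 of its markers, each detected in 10% of its cells, were 2-fold above the other clusters. Where several lists met this, the name went to the list with both the most markers and the largest share of its measured markers, if at least 1 was among the cluster's 10 leading genes and no other list had more there. The cluster led by Ly6c2, with 5 monocyte/macrophage and 3 neutrophil markers, was thus called monocyte-like. In another cluster no list led by both, and its name (erythroid, megakaryocyte and mast markers) was set after its markers had been seen. Class names describe marker transcripts and were not checked by surface protein. Shares of cells were tested with edgeR on cell counts, and an exact two-sided permutation of the 4 libraries stands beside. Within a class, UMIs were summed per library and fitted as above where every library held at least 50 cells. Differences of the genotype effect between classes were tested with edgeR, with the library as a factor and the interaction of class and genotype.

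For detection of lineage regulators, each cell was thinned at random to 4346 UMIs, the 10th percentile of UMIs per cell, and shallower cells were left out. Background was read in a class assumed to lack the gene.

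The fits were tested on simulated data with 200 genes changed. Over all cells, 94% of genes changed 1.5-fold and 32% of those changed 1.25-fold were recovered, and 17 of 3422 unchanged genes were called. Within classes, 76% to 90% of 1.5-fold changes were recovered, and 66% to 82% for differences between classes. In HSPC-like, basophil/mast-like and monocyte-like cells 13, 11 and 17 unchanged genes were called, again above that share. Simulated genes varied independently of each other. Depth and the number of libraries were not varied in this simulation.

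Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, no filter, equal cells per library, the 20 genes with most UMIs left out of the library size, each library left out, clustering at resolution 0.5 and 2.0, clustering without the changed genes, classes by the highest marker score per cell, and other thinning depths. A term for Xist, library sums thinned to equal UMIs, and clustering after thinning were added after seeing the data. The doublet caller (Scrublet) marked only 0.0329% to 0.313% of cells per library at an expected rate of 5% and so did not work. Class shares were recomputed without these 11 cells, which does not amount to a removal of doublets, and doublets stayed in all other results. No block by replicate number was fitted, since no label ties the letters to these numbers. The term for Xist groups F with A and I with B. Leaving out a library leaves a genotype with a single library, which is assumed to vary like the other genotype.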

Results

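Single-cell RNA sequencing on the 10x Genomics Chromium platform measured transcripts in progenitors sorted from mouse fetal liver at E14.5. The sort gate (Lin-Sca1-Kit+CD34+) kept cells with Kit and CD34 and without Sca1 or lineage markers. Libraries F and I came from wild-type embryos, and libraries A and B from embryos without -77, an enhancer upstream of Gata2, so n = 2 per genotype. These letters are the deposited ones, and none is tied to a sample number. The series describes separate embryos, and if they were not separate, the p-values measure only the spread between these libraries. Library F held 3042 cells and 40117680 UMIs, with a median of 12826.5 UMIs per cell. Library I held 1938 cells and 33913118 UMIs, with a median of 17437.5. Library A held 2235 cells and 16837863 UMIs, with a median of 7492, and library B held 2745 cells and 19921052 UMIs, with a median of 7087. The median over all cells was 1.97 times higher in the wild type. Mitochondrial transcripts took 3.07% to 3.35% of UMIs and ribosomal protein transcripts 34.3% to 37.0%. Xist, the transcript of the inactive X chromosome, reached 492 CPM (UMIs scaled to the library's panel total) in library I, 410 in B and 0.0249 in F. Library A had 0 Xist UMIs, which allows up to 0.178 CPM.

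The comparison of genotypes over all cells asked which transcripts depend on the enhancer, be it within cells or through the mix of cells. Gata2, a zinc finger transcription factor of hematopoietic stem and progenitor cells, was lower in both enhancer-deleted libraries. It reached 26.3 CPM in library F and 23.2 in I, against 7.48 in A and 6.73 in B. The means were 24.7 ± 2.22 and 7.10 ± 0.535 (SD, n = 2 each), a 3.62-fold difference (log2 fold change -1.86, SE 0.19, edgeR adjusted p = 0.00792). Gata2 (ENSMUSG00000015053.14) lies on the + strand of chromosome 6 from 88193891 to 88207032, in mm10 coordinates. The deleted sequence is outside this transcript, so the counts do not read the deletion itself. Without library A the adjusted p was 0.0545 at a log2 fold change of -1.98, and over 12 alternatives it ran from 9.65e-21 to 0.0545.

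**Figure D1:**
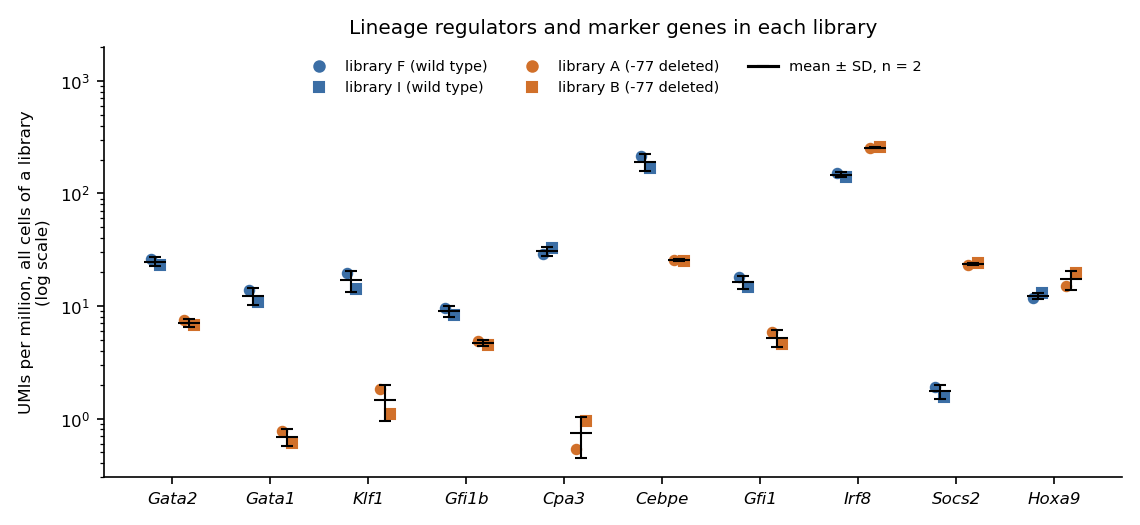
Levels of 10 genes over all cells of each library, in CPM on a log scale. Points are libraries (n = 2 per genotype) and bars the mean and SD; Gata2 stands at 26.3 and 23.2 in the wild type and at 7.48 and 6.73 in the enhancer-deleted libraries, and Socs2 and Irf8 stand higher in both enhancer-deleted libraries (Cpa3, Socs2 and Hoxa9 were added to the plot after their values had been seen).

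Erythroid, mast cell and neutrophil transcripts fell in the enhancer-deleted libraries. These sums over all cells mix the share of each cell class with the level within it. Gata1, the transcription factor of erythroid and megakaryocyte differentiation, fell 18.6-fold, from 12.3 ± 2.12 to 0.687 ± 0.120 CPM (n = 2 each). The alpha globins Hba-a1 and Hba-a2 fell 9.12-fold and 10.3-fold. Cpa3, a mast cell carboxypeptidase, fell 41.7-fold, from 30.6 ± 2.73 to 0.744 ± 0.296, and Hdc, the enzyme that makes histamine, fell 13.3-fold, from 46.1 ± 3.08 to 3.58 ± 0.113. Camp, an antimicrobial peptide of neutrophil granules, fell 145-fold, from 241 ± 171 to 1.72 ± 0.334. S100a8 and S100a9, the calprotectin subunits of neutrophils and monocytes, fell 13.1-fold and 23.1-fold. Fcnb, a ficolin of myeloid cells, fell 14.6-fold, and Gm5483 and BC100530 fell 95.9-fold and 27.0-fold. Camp also differed between the wild-type libraries, at 362 in F and 120 in I. Without library A the adjusted p was 0.0750 for Camp, 0.0565 for Gm5483, 0.0708 for S100a9, 0.0784 for Fcnb and 0.0572 for Gata1, and without library B it was 0.0707 for Fcnb. Over the alternatives of Camp it ran from 8.18e-17 to 0.0750. Within erythroid-like cells alone, Hba-a1 stood at 31463 and 58282 CPM in libraries F and I. It stood at 32215 and 57671 in A and B, which held 3 such cells each. Within neutrophil-like cells S100a8 stood at 9278 and 9210 in F and I, and at 6279 and 5337 in A and B.

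Fewer genes rose, and by less. Socs2, a suppressor of cytokine receptor signalling on chromosome 10, rose 12.96-fold, from 1.74 ± 0.252 to 23.5 ± 0.631 CPM (n = 2 each, edgeR adjusted p = 0.00359). Of 9 other measured genes within 2 megabases of it, Lta4h and Gm15915 fell. Cox4i2, a subunit of cytochrome c oxidase, rose 2.37-fold, from 36.4 ± 1.09 to 89.6 ± 10.9. Trem2, a receptor of macrophages, rose 2.37-fold, from 9.10 ± 0.849 to 22.2 ± 3.06. The interferon-induced genes Ifi203 and Ifitm3 rose 2.03-fold and 1.73-fold. H2-DMa of antigen presentation rose 1.73-fold, the GTPase genes Gimap1 and Gimap6 1.72-fold and 1.69-fold, and Ccnd1 (cyclin D1) 1.70-fold. Without library A the adjusted p was 0.178 for Trem2, 0.0878 for Ifitm3, 0.0742 for H2-DMa, 0.0509 for Gimap1 and 0.0868 for Gimap6. Without library B it was 0.111 for Trem2, 0.0685 for Gimap1 and 0.0758 for Gimap6.

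In all, 321 of 3622 genes passed the edgeR test, 100 higher and 221 lower in the enhancer-deleted libraries, at a biological coefficient of variation of 0.0924. In 1958 genes (54.1%) both libraries of a genotype lay above both of the other, against 33.3% by chance. Without library A 66 genes passed and without library B 112, while the DESeq2 Wald test passed 734 and the fit with a term for Xist 481 (159 higher and 322 lower). For a single value, 2 libraries against 2 cannot reach an exact permutation p below 0.333.

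Transcripts of the erythroid program fell as a group. All 15 measured erythroid genes fell (15 adjusted over the list alone), among them Car2 (carbonic anhydrase 2, 74.6 ± 6.87 to 32.4 ± 1.27 CPM), Hba-a1 and Blvrb (43.6 ± 3.47 to 12.6 ± 0.846). Its camera adjusted p was 1.93e-17, and the adjusted p = 0.220 with an estimated correlation. Of 9 heme synthesis genes 6 fell (6 adjusted over the list alone), including Alas1, which starts heme synthesis (90.1 ± 5.08 to 22.0 ± 0.241), its erythroid form Alas2 (9.85 ± 5.37 to 0.425 ± 0.180) and the mitochondrial iron importer Slc25a37 (33.7 ± 2.34 to 20.7 ± 0.242). Camera gave an adjusted p of 2.08e-07, and the adjusted p = 0.220 with an estimated correlation. Alas1 was not limited to erythroid-like cells, as within monocyte-like cells it fell from 95.5 ± 25.4 to 31.5 ± 4.10. Its fall is therefore not specific to the erythroid program. None of the 4 measured megakaryocyte genes passed the edgeR test (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 past the DESeq2 Wald test, camera adjusted p = 0.192). Levels were 8.36 ± 6.57 and 2.20 ± 0.415 for Pf4 and 7.80 ± 1.69 and 5.85 ± 0.0375 for Gp9 in wild-type and enhancer-deleted libraries. Pf4 had an edgeR p of 0.0322 before adjustment and 0.160 after it, and passed without library I (adjusted p = 0.00671), in the DESeq2 Wald test (0.0155) and with a term for Xist (0.0241). Only 4 of 14 genes of this list were in the panel. Without library A the adjusted p was 0.106 for Alas2 and 0.0852 for Slc25a37, and without library B 0.0781 and 0.0930.

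Most basophil/mast and neutrophil genes were lower too. Of 5 basophil/mast genes 4 fell (4 adjusted over the list alone), namely Hdc, Cpa3, Ms4a2 and Lmo4 (88.1 ± 3.56 to 46.5 ± 2.90 CPM). The remaining member, the basophil protease Mcpt8, was at 12.2 ± 1.68 and 15.4 ± 2.52 and did not pass. The camera adjusted p was 0.000160, and the adjusted p = 0.344 with an estimated correlation. The eosinophil granule genes Prg3 (16.6 ± 0.133 to 0.413 ± 0.0875) and Prg2 (17.8 ± 11.2 to 0.0297 ± 0.0420) both fell, and no other gene of that list was measured. Of 14 neutrophil genes 12 fell (14 adjusted over the list alone). Cebpe, a transcription factor of granulocyte maturation, fell 7.80-fold from 191 ± 33.8 to 25.4 ± 0.514, Ms4a3 from 632 ± 97.5 to 208 ± 10.6, and Mpo (myeloperoxidase) from 1529 ± 26.2 to 860 ± 114. The camera adjusted p was 3.29e-12, and the adjusted p = 0.411 with an estimated correlation. Nkg7, the measured gene of the T/NK/ILC list, fell from 213 ± 63.7 to 94.0 ± 2.65. Here it marked both neutrophil-like clusters, and no T/NK/ILC class formed, so its fall does not show a loss of such cells. Without library A the adjusted p was 0.0755 for Prg2 and 0.135 for Nkg7, and without library B 0.0508 and 0.129.

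Stem cell, monocyte and interferon response genes were higher in part. Of 8 HSPC/multipotent genes 3 rose (4 adjusted over the list alone), the transcription factor Sox4 (60.9 ± 0.647 to 92.4 ± 7.43 CPM), the homeobox gene Hoxa7 (21.5 ± 1.07 to 35.5 ± 1.21) and the receptor Cd27 (41.0 ± 1.01 to 58.4 ± 1.81). The camera adjusted p was 0.000160, and the adjusted p = 0.258 with an estimated correlation. Of 12 monocyte/macrophage genes 3 rose (6 adjusted over the list alone, 5 of them higher). Irf8, a transcription factor of monocytes and dendritic cells on chromosome 8, rose 1.68-fold from 147 ± 8.49 to 256 ± 0.929 (edgeR adjusted p = 0.00980). Csf1r, the receptor for macrophage colony-stimulating factor, rose from 30.2 ± 0.885 to 47.7 ± 3.62, and Ms4a6c from 94.4 ± 3.59 to 139 ± 14.48. The monocyte marker Ly6c2 went the other way, from 189 ± 54.8 to 59.3 ± 27.3, and passed only within the list (adjusted p = 0.0544 over all genes). The camera adjusted p was 0.0455, and the adjusted p = 0.784 with an estimated correlation. Of 7 interferon response genes 2 rose, Ifi203 and Ifitm3 (2 adjusted over the list alone), and Bst2 was at 167 ± 6.88 and 199 ± 21.02. The camera adjusted p was 0.0111, and the adjusted p = 0.723 with an estimated correlation. Without library A the adjusted p was 0.0509 for Sox4, 0.110 for Hoxa7, 0.142 for Cd27, 0.0592 for Irf8, 0.118 for Csf1r and 0.0868 for Ms4a6c. Hoxa7 (0.122) and Cd27 (0.0685) also missed the threshold without B, Cd27 (0.0696) without I, and Csf1r and Ms4a6c without F (0.0547 and 0.0907) and without I (0.0537 and 0.135).

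Of 26 hematopoietic transcription regulators 7 fell and 2 rose (15 adjusted over the list alone). Besides Cebpe, Gata1 and Gata2, Myb, a regulator of progenitor proliferation, fell from 148 ± 1.52 to 88.5 ± 0.304 CPM, and Irf8 and Ikzf1 rose. The camera adjusted p was 0.0396 downward, and the adjusted p = 0.784 with an estimated correlation. Camera missed its threshold for the monocyte/macrophage list without library A (0.595), for the regulators without F (0.127) and B (0.0937), and for the interferon list without I (0.0788). Of 7 growth factor receptors the interferon gamma receptor Ifngr1 (101 ± 0.865 to 57.0 ± 3.01) and the GM-CSF receptor Csf2ra (37.3 ± 2.17 to 23.3 ± 0.570) fell and Csf1r rose (4 adjusted over the list alone, camera adjusted p = 0.451). Of 7 innate immune genes the Fc receptor Fcgr3 (202 ± 19.6 to 74.0 ± 0.107) and the lectin Clec4a2 (33.3 ± 7.88 to 5.34 ± 1.44) fell (2 adjusted over the list alone, camera adjusted p = 0.451), and Fcgr1 rose in the DESeq2 Wald test only (0.0440). Without library A the adjusted p was 0.0509 for Clec4a2 and 0.0872 for Csf2ra, which was at 0.113 without B.

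Cell cycle and housekeeping lists had no gene past the edgeR threshold with all 4 libraries. These were 19 S phase genes (camera adjusted p = 0.312), 19 G2/M genes (0.0691), 18 ribosomal protein genes (0.451) and 3 immediate early genes (0.754), each with 0 genes adjusted over the list alone. Without library F the S phase genes Mcm5 (log2 fold change -0.37, adjusted p = 0.0386) and Cdc45 (-0.58, adjusted p = 0.0312) passed. At an unadjusted p under 0.05 there were 1, 3, 0 and 1 genes of these lists, and the DESeq2 Wald test passed 0, 2, 0 and 1. Mcm5 of the S phase list was at 109 ± 16.3 and 94.4 ± 0.692 CPM, and Aurkb of the G2/M list at 81.8 ± 1.41 and 74.9 ± 2.77. Camera passed downward for G2/M without library F (adjusted p = 0.00790) and for ribosomal protein and megakaryocyte genes without library I (0.0375 and 0.00731). Cd74 (dendritic), Cd79b and Ebf1 (B lymphoid), Stab2 (endothelial), Hmox1 (mature liver macrophage) and Xist (sex-linked) did not pass, and no hepatoblast or stromal gene was in the panel.

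**Figure D2:**
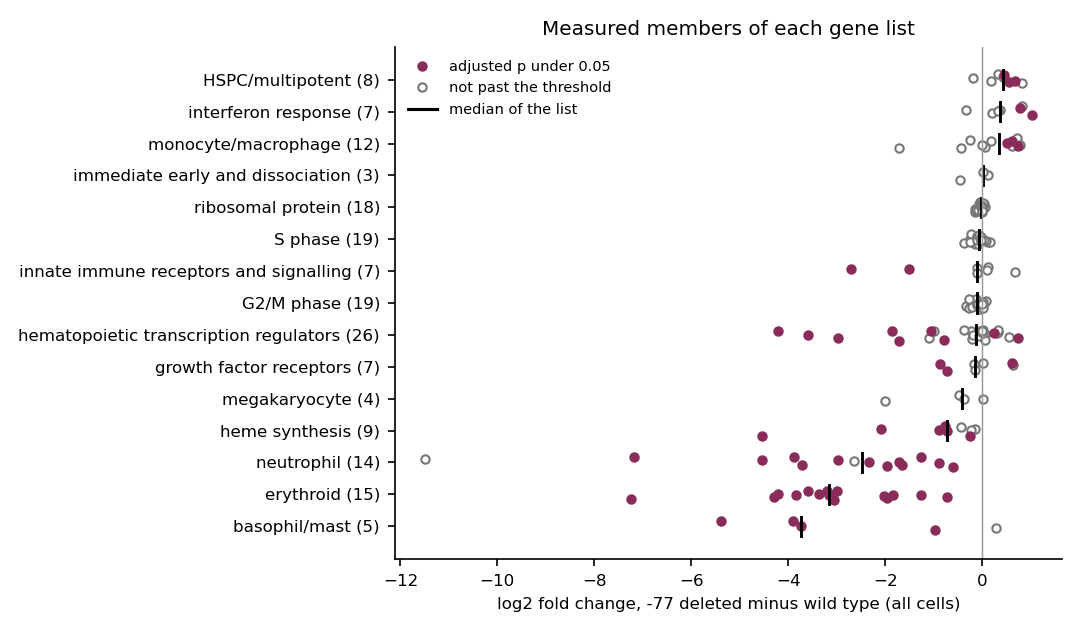
Log2 fold change (enhancer-deleted minus wild type, all cells) of the measured genes of each list, with their number in brackets. Filled points passed the edgeR test and black lines are list medians; all 15 erythroid genes lie below 0, and the leftmost point, Ngp, had 0 UMIs in both enhancer-deleted libraries, so its place depends on the fit.

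The share of cells with a UMI of a lineage regulator was compared after thinning each cell to 4346 UMIs, which left out 140 wild-type and 855 enhancer-deleted cells. Gata2 was detected in 8.84% ± 0.243 of wild-type and 2.88% ± 0.378 of enhancer-deleted cells (n = 2 each). Neutrophil-like cells, assumed to lack it, gave 2.31% (27 of 1168 cells) and 2.70% (2 of 74 cells), and 74 cells are too few to tell the enhancer-deleted share from background. This class also held a cluster led by the eosinophil genes Prg2 and Prg3 and marked by Hdc, so its lack of Gata2 was not shown. Median depths before thinning were 12761.5 and 6412 UMIs in that class, against 14483.5 and 8063 in all cells kept. Without thinning Gata2 was detected in 19.3% and 4.99% of cells. Gata1 fell from 5.37% ± 0.180 to 0.240% ± 0.0315, and Klf1, another erythroid transcription factor, from 4.57% ± 0.913 to 0.349% ± 0.123 (9.36% to 0.321% and 7.84% to 0.589% without thinning). Monocyte-like cells gave 0.340% and 0 of 1004 cells for Gata1, which allows up to 0.299%, and 0.680% and 0.0996% for Klf1, at median depths of 18777 and 8010.5 UMIs. Irf8 was detected in 29.8% ± 0.148 and 54.1% ± 1.78 of cells and Cebpe in 34.8% ± 3.08 and 7.85% ± 0.905 (45.8% and 63.2%, and 47.6% and 10.7%, without thinning). Wild-type erythroid-like cells gave 2.38% for Irf8 and 1.19% for Cebpe at a median of 10559.5 UMIs, and only 6 such cells were left in the enhancer-deleted libraries. Spi1, the myeloid regulator PU.1, was at 73.2% ± 1.49 and 78.1% ± 0.708 after thinning, and at 91.4% and 86.3% without it, so its order differed with and without thinning, and no class that should lack Spi1 or Runx1 was set as background. Each of these differences except that of Runx1 (26.8% ± 1.82 and 28.7% ± 1.38, exact permutation p = 0.667) separated the genotypes, with the smallest exact permutation p possible. Runx1 turned as well, at 46.8% and 45.1% after thinning to the median and 59.4% and 41.7% without thinning (exact permutation p = 0.333 in both).

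The share of cells in each class asked which developmental paths the deletion changes, within the sorted gate and after the subsampling to equal cells per genotype. Neutrophil-like cells made up 22.9% ± 8.07 of wild-type and 1.93% ± 0.819 of enhancer-deleted libraries (n = 2 each), an 11.9-fold lower share (edgeR adjusted p = 0.00724). This class joined a cluster led by Camp and another led by the eosinophil genes Prg2 and Prg3. The latter held 53.4% of the class in the wild type and 60.2% in the enhancer-deleted libraries. Erythroid-like cells fell 14.51-fold, from 1.77% ± 0.128 to 0.122% ± 0.0176 (adjusted p = 0.00202). A cluster with erythroid, megakaryocyte and mast cell markers, led by Gm15915, Car1, Pf4 and Gata1, fell 38.8-fold, from 6.47% ± 1.41 to 0.167% ± 0.0809 (adjusted p = 0.00202). Its cells numbered 227 and 106 in libraries F and I, and 5 and 3 in A and B. HSPC-like cells, marked by Hlf, Meis1, Mycn and Hoxa7, were at 21.6% ± 1.10 and 34.6% ± 1.89, a 1.60-fold higher share (adjusted p = 0.0221). The shares of a library add up to its whole, so large falls raise the shares of the other classes. A higher share here or below therefore does not show that a class gained cells.

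Basophil/mast-like cells, marked by Mcpt8, Cpa3 and Hdc, fell 2.12-fold, from 11.96% ± 0.312 to 5.64% ± 0.00640 (n = 2 each, edgeR adjusted p = 0.00724). Monocyte-like cells were at 18.5% ± 4.59 and 22.6% ± 1.37 (adjusted p = 0.329). In the wild type 69.1% of them came from a cluster led by Ly6c2 that also held the neutrophil markers Elane, Ctsg and Ms4a3. In the enhancer-deleted libraries that cluster held 32.5% of the class, and clusters led by Trem2 and by Ccr2 held 41.0% and 26.5%. A cluster led by Irf8 and Ms4a6b, with too few markers for a class name, rose 2.56-fold, from 4.56% ± 0.919 to 11.7% ± 0.155 (adjusted p = 0.00891). The clusters numbered 4 and 12, with median depths of 3940 and 2529 UMIs per cell, rose from 1.31% ± 0.897 to 7.56% ± 2.60 (adjusted p = 0.0290) and from 1.22% ± 0.324 to 2.77% ± 0.827 (adjusted p = 0.0430). The unnamed clusters 2 and 10 were at 5.29% ± 2.37 and 8.13% ± 3.08 (adjusted p = 0.321), and at 4.40% ± 0.640 and 4.88% ± 0.884 (adjusted p = 0.533).

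Several class markers were themselves among the changed genes, so the cells were also clustered without these genes. Neutrophil-like cells were then at 24.3% and 2.84% (8.55-fold, edgeR adjusted p = 0.000185), erythroid-like cells at 1.81% and 0.0994% (18.2-fold, adjusted p = 9.14e-05) and the mixed marker cluster at 2.76% and 0.0447% (61.7-fold, adjusted p = 9.14e-05). HSPC-like cells were at 14.7% and 19.97% and no longer passed (adjusted p = 0.245), and monocyte-like cells were at 19.6% and 25.6% (adjusted p = 0.311). Basophil/mast-like cells shrank to 39 and 17 cells of libraries F and I and 0 of 4980 enhancer-deleted cells, which allows up to 0.0602%. At clustering resolution 2.0 basophil/mast-like cells were at 4.93% and 0.333% (14.8-fold). By the highest marker score per cell, erythroid-like cells were at 5.61% and 5.00% (adjusted p = 0.441), and monocyte-like cells rose from 19.4% to 33.1% (adjusted p = 0.000780). By that score neutrophil-like cells fell 3.36-fold, from 31.4% to 9.34%. Megakaryocyte-like cells, a class that clustering did not form, rose from 10.4% to 14.9% (adjusted p = 0.0145). Leaving out a library ended the call for HSPC-like cells (adjusted p = 0.0662 without F, 0.0530 without I, 0.202 without A and 0.324 without B). It also ended the call for neutrophil-like cells (0.0662 without F, 0.0516 without I), basophil/mast-like cells (0.126 without A, 0.112 without B), cluster 4 (0.0662 without F, 0.111 without I) and cluster 12 (0.268 without F, 0.120 without I, 0.202 without A). For HSPC-like cells the adjusted p ran from 0.000780 to 0.324 over the alternatives, and for erythroid-like cells from 4.77e-06 to 0.441.

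**Figure D3:**
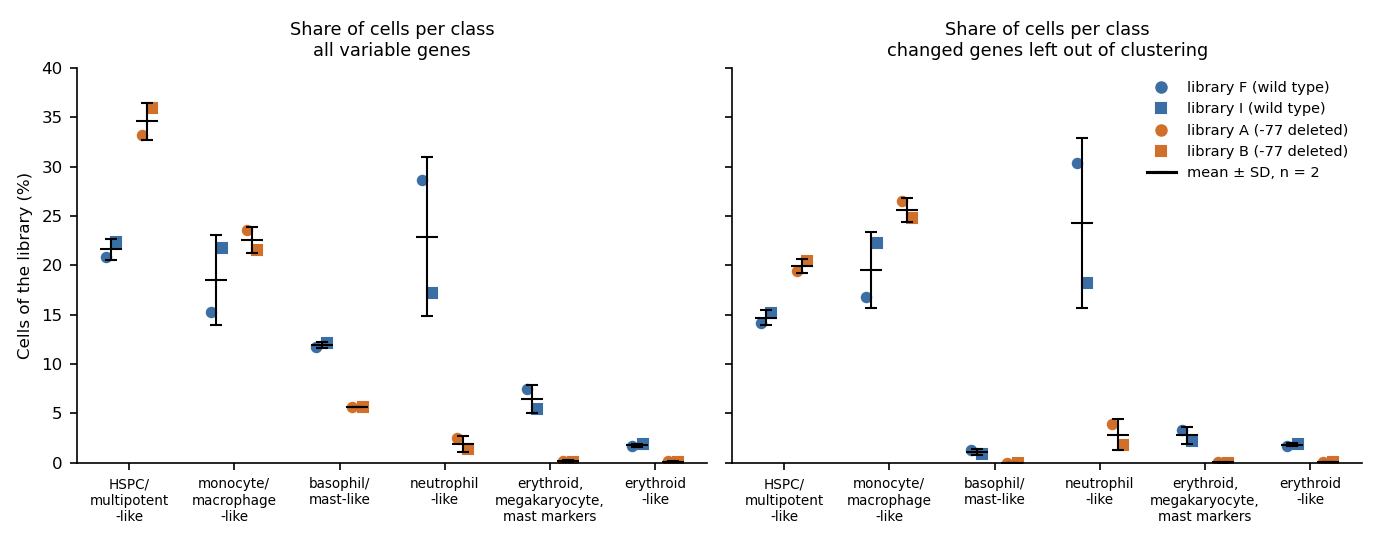
Share of each library's cells (%) in 6 classes, clustered with all variable genes (left) and without the changed genes (right). Points are libraries (n = 2 per genotype) and bars the mean and SD; neutrophil-like, erythroid-like and mixed marker cells lie lower in both enhancer-deleted libraries in both panels.

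Within HSPC-like cells, Socs2 rose most and Cpa3 fell most among genes past the threshold with at least 20 CPM in the higher group. Socs2 rose 12.8-fold, from 4.68 ± 0.267 to 62.2 ± 2.99 CPM (n = 2 each, edgeR adjusted p = 0.000232). Cox4i2 rose 1.99-fold, the noncoding RNA Gm26917 1.66-fold, and Cd24a, a surface glycoprotein, 1.57-fold, from 142 ± 8.36 to 230 ± 22.1. The beta globin Hbb-bt rose 1.75-fold, from 128 ± 15.8 to 230 ± 1.26 (adjusted p = 0.0186), while it fell over all cells, from 788 ± 229 to 199 ± 13.2. Cpa3 fell 33.5-fold, from 32.7 ± 0.293 to 0.971 ± 0.340, Apoe (apolipoprotein E) 6.53-fold, from 329 ± 65.6 to 52.1 ± 11.9, and Smim5 2.39-fold. Gata2 fell 2.94-fold, from 35.6 ± 2.53 to 12.5 ± 0.373 (adjusted p = 0.0154). S100a8 fell 6.61-fold, from 52.8 ± 19.3 to 8.37 ± 1.34, and in library F it stood near 66.4 in these cells, 66.5 in cluster 2 and 71.2 in the mixed marker cluster. All other classes and clusters of F stood higher. They ran from 78.6 in cluster 0 to 9278 in neutrophil-like cells, with 97.3 in basophil/mast-like cells and 149 in cluster 10. In all 30 of 3576 genes passed, 7 higher and 23 lower. Without library F 5 genes passed, without I 6 and without A 97. The genes lost without F (Cd24a, Gata2, Gm26917, Hbb-bt and Smim5) had adjusted p-values from 0.0576 to 0.0766. Those lost without I (the same genes and Cox4i2) had 0.0526 to 0.124, and Cd24a and Smim5 without B 0.0535 and 0.0537. At clustering resolution 0.5 11 genes passed. Gata2 was at adjusted p = 0.0702 there and 0.0532 at 2.0, within a range of 9.41e-08 to 0.0702. S100a8 (0.0702 and 0.0743), Cd24a (0.0702 and 0.101) and Smim5 (0.101 and 0.0780) also missed the threshold at both resolutions. In HSPC-like cells clustered without the changed genes, Hbb-bt was at 122 and 137 CPM in F and I. It was at 464 and 248 in A and B there, so its size and spread depended on the class borders.

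Within basophil/mast-like cells, Cpa3 and Hdc fell and Mcpt8 and Irf8 rose. Cpa3 fell 42.0-fold, from 90.8 ± 12.8 to 2.14 ± 0.808 CPM (n = 2 each), Hdc 10.0-fold, from 67.8 ± 7.80 to 7.04 ± 2.27, Perp 11.5-fold, Apoe 5.52-fold, and Gata2 4.61-fold, from 27.9 ± 0.767 to 6.31 ± 2.20 (edgeR adjusted p = 0.00313). Irf8 rose 2.26-fold, from 73.9 ± 20.8 to 174 ± 8.71, and Mcpt8, the basophil protease, 2.15-fold, from 22.6 ± 0.279 to 50.4 ± 2.13. Cd24a rose 2.83-fold, and the interferon-induced genes Ifi203 and Mndal 2.56-fold and 2.299-fold. In all 161 of 3555 genes passed, 44 higher and 117 lower. Without library F 88 genes passed, without I 89, without A 94 and without B 19, and the DESeq2 Wald test passed 74 (Mndal missed it, at 0.0547). Cpa3, Hdc and Mcpt8 also marked the class. At resolution 2.0 it held 165 and 86 cells of libraries F and I and 10 and 6 of A and B, so different kinds of cells within the class were not separated from a change within a cell. Without library B, Cd24a, Gata2, Ifi203, Irf8, Mcpt8, Mndal and Perp had adjusted p-values from 0.0776 to 0.296. Without A, Irf8, Mcpt8 and Mndal had 0.0565 to 0.0978, and Mndal had 0.0626 without F and 0.0974 without I.

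Within monocyte-like cells, 3 of 12 monocyte/macrophage genes rose and 6 of 13 neutrophil genes fell. Trem2 rose 2.36-fold, from 29.2 ± 0.929 to 68.1 ± 5.36 CPM (n = 2 each, edgeR adjusted p = 0.00813). Cx3cr1, the fractalkine receptor, rose 2.13-fold, from 22.3 ± 2.10 to 47.1 ± 8.04, Nrp1 (neuropilin) 2.22-fold, Tsc22d1 2.19-fold and St3gal5 2.11-fold. Cebpe fell 3.49-fold, from 134 ± 28.7 to 37.9 ± 0.431 (adjusted p = 0.00520), S100a8 3.80-fold, from 1016 ± 32.0 to 262 ± 116, Fcnb 4.38-fold, Hdc 5.26-fold and Alas1 from 95.5 ± 25.4 to 31.5 ± 4.10. The 3 clusters of this class took different shares in the genotypes, as given with the class shares. A change in the mix of clusters was thus not separated from a change within a cell. In all 62 of 3572 genes passed, 21 higher and 41 lower, and 332 without library F, 119 without I and 136 by the DESeq2 Wald test. Without library A, Cx3cr1, St3gal5 and Tsc22d1 had adjusted p-values from 0.0587 to 0.0981, and without B, Fcnb, Hdc, St3gal5 and Tsc22d1 had 0.0607 to 0.156. At clustering resolution 0.5 5 of the 10 genes named here missed the threshold (0.0511 to 0.187), and 3 did at 2.0 (0.0554 to 0.0972). Neutrophil-like cells (37 in library B), erythroid-like cells and the mixed marker cluster were too few for this test.

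The genotype effect was compared between classes by an interaction test in edgeR. This test does not separate a change within cells from a different mix of cells within a class. It passed for 253 of 3594 genes between HSPC-like and basophil/mast-like cells, 564 of 3599 between HSPC-like and monocyte-like cells, and 482 of 3587 between basophil/mast-like and monocyte-like cells. The effect on Gata2 itself was not shown to differ between classes, at differences of -0.64 (SE 0.38, adjusted p = 0.330), 0.48 (SE 0.52, adjusted p = 0.585) and 1.13 (SE 0.61, adjusted p = 0.226) for these pairs on the log2 scale, the second class minus the one before it.

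**Figure D4:**
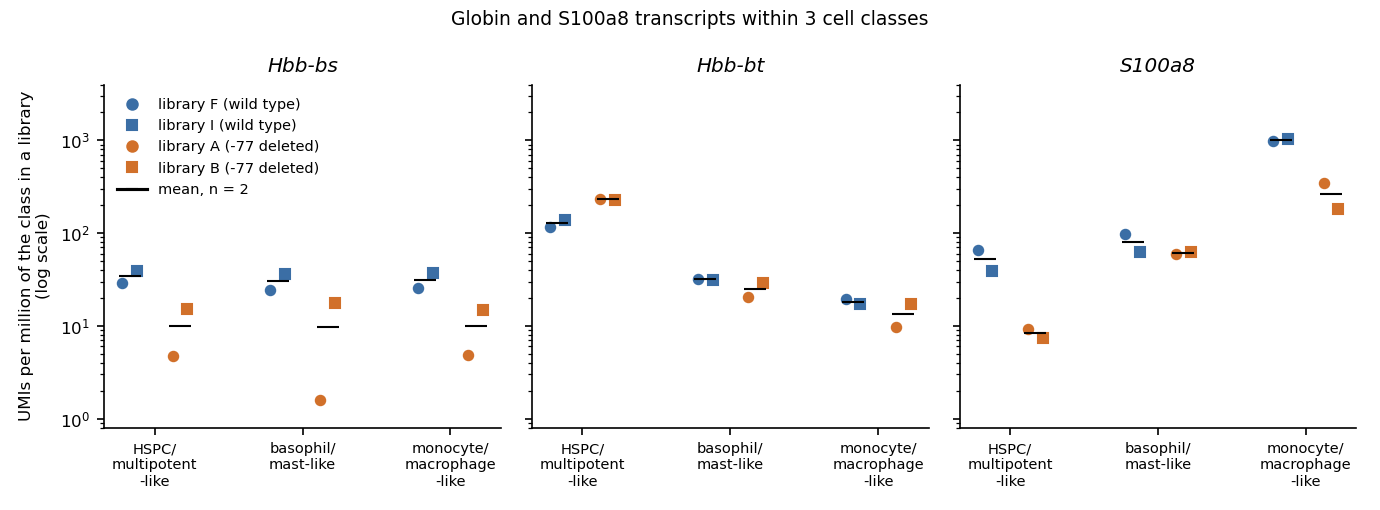
CPM (log scale) of Hbb-bs, Hbb-bt and S100a8 within 3 classes of cells. Points are libraries and lines the mean of n = 2; Hbb-bt lies higher in the enhancer-deleted libraries in HSPC-like cells (128 against 230), while Hbb-bs lies lower in all 3 classes.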

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

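The tests of the globin genes and of Socs2 within HSPC-like cells were chosen after their results had been seen, as was clustering after thinning. Of the 24 genes named within a class, 12 had a genotype effect that differed between classes by the edgeR interaction test. Each is given as the log2 difference of the effect, from 4 libraries, for the pair of classes with the smallest p. The test borrows the spread of other genes, so its very small p-values do not stand for more than these 4 libraries. The 24 genes were named for a large effect in a class from these same counts, which favours a difference. Over all genes the interaction test passed for 253 of 3594, 564 of 3599 and 482 of 3587, depending on the pair.

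In basophil/mast-like cells minus HSPC-like cells, the effect differed by -1.18 for Hbb-bt (SE 0.19, adjusted p = 2.94e-06), which rose 1.75-fold in HSPC-like cells. Irf8 differed by 0.80 (SE 0.12, adjusted p = 2.33e-07) and Cd24a by 0.86 (SE 0.13, adjusted p = 1.69e-06), and both rose in basophil/mast-like cells, while in HSPC-like cells Cd24a rose by less and Irf8 did not pass (adjusted p = 0.387). Ifi203 differed by 1.26 (SE 0.20, adjusted p = 2.94e-06) and Mndal by 1.51 (SE 0.26, adjusted p = 1.04e-05). S100a8 differed by 2.302 (SE 0.20, adjusted p = 4.43e-16), since it fell in HSPC-like cells and stayed at 59.7 and 63.1 CPM in the basophil/mast-like cells of libraries A and B.

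In monocyte-like minus HSPC-like cells, Alas1 differed by -0.95 (SE 0.21, adjusted p = 0.00466) and Cx3cr1 by 1.06 (SE 0.23, adjusted p = 0.00436). St3gal5 differed by 1.14 (SE 0.25, adjusted p = 0.00456) and Tsc22d1 by 1.38 (SE 0.16, adjusted p = 1.91e-05). In monocyte-like minus basophil/mast-like cells, Mcpt8 differed by -1.25 (SE 0.27, adjusted p = 0.00210) and Apoe by 2.51 (SE 0.11, adjusted p = 4.22e-19).

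Within HSPC-like cells S100a8 fell and Hbb-bt rose, though S100a8 missed the threshold at clustering resolution 0.5 and 2.0 (adjusted p = 0.0702 and 0.0743). Free RNA of erythroid cells does not account for Hbb-bt, since only 1 of 12 log2 ratios (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt in 3 classes) lay above 0, that of Hbb-bt in HSPC-like cells. Class borders set by the deeper wild-type libraries do not account for S100a8, whose log2 ratio was -2.58 with classes from thinned counts and -2.66 without thinning. Free RNA of neutrophil-like cells is a candidate source of the S100a8 part. In library F the shares of 6 granule genes among themselves differed between HSPC-like and neutrophil-like cells by a median absolute log2 difference of 0.105. In library I the median was 0.564, but Ngp and Lcn2 had 0 UMIs and Fcnb 5 in HSPC-like cells there, so library I decides little. A genotype effect on Hbb-bt in these cells stays open as a hypothesis, and so does one on S100a8 beside free RNA.

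Socs2 rose over all cells by 3.70 on the log2 scale. A higher share of HSPC-like cells does not account for it, since it rose by 3.68 within them. A difference in the chromosome region around Socs2 cannot be told apart from an effect of the enhancer: 2 of 9 measured genes within 2 megabases passed (Lta4h and Gm15915, both lower), with a one-sided Fisher exact p of 0.189, and 9 genes are too few to decide. Gm15915 also led the mixed marker cluster, whose share fell 38.8-fold, so its pass over all cells need not reflect the region. An effect of the genotype may raise Socs2 and was not separated from such a linked difference.

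The share of cells in clusters 4 and 12 together was higher in the enhancer-deleted libraries, by 2.03 on the log2 scale. These cells held 0.495 to 0.565 (cluster 4) and 0.277 to 0.309 (cluster 12) of their library's median UMIs. Fewer UMIs per cell in the enhancer-deleted libraries may be the source: after thinning to equal median UMIs the log2 ratio of the matching cluster was 1.09 (SE 0.31), which lies within that error of 1.02, the value that would remain if depth gave 0.5 of it. That cluster still stood higher after thinning, at 8.10% and 5.68% in A and B against 3.75% and 2.73% in F and I (edgeR adjusted p = 0.0203). Depth was thus not shown to be the whole source. Its part and that of genotype cannot be told apart here, because wild-type and enhancer-deleted libraries differ in depth throughout.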

How the results depend on the processing

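A term for Xist, library sums thinned to equal UMIs, and clustering after thinning were chosen after seeing the data, and the other alternatives before. Over all cells, 67 named genes were recomputed under up to 12 alternatives: 746 of 801 values kept direction and side of the threshold, 39 lost the call, 9 gained it and 7 turned. No called value turned. Ier2 turned to a log2 fold change of -0.0134 after thinning the libraries to equal UMIs. With a library left out, the log2 fold changes ran from -15.83 to 12.63 for Xist (near 0 in F and A), -0.19 to 1.38 for Cd74, -0.72 to 0.0323 for Hmox1 and -0.0570 to 0.0879 for Ier2. The log2 ratio of shares of cluster 10 ran from -0.0451 to 0.33. The camera direction also turned, without a call, for ribosomal protein and immediate early genes, whose adjusted p ran from 0.0375 (downward) to 0.831 and from 0.367 to 0.998. The losses came from leaving out a library, 23 of them library A and 11 library B. Within classes, 201 of 250 values kept both and 49 lost the call. The cause was not tested for the values below unless given. The count over all cells was 734 with the DESeq2 Wald test, 481 with a term for Xist and 66 to 291 with a library left out. Of the 321 genes, 294 passed again after thinning the libraries to equal UMIs and 319 with a term for Xist. Within HSPC-like cells the count was 46 with the DESeq2 Wald test, 11 at clustering resolution 0.5 and 5 to 97 with a library left out. It was 74 and 19 to 94 in basophil/mast-like cells, and 136 and 43 to 332 in monocyte-like cells, for the DESeq2 Wald test and with a library left out. Leaving out a library leaves 3 libraries.

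For Gata2 the log2 fold change was -1.98 to -1.73 with a library left out, and the call was lost without A (adjusted p = 0.0545). Its detection difference was -5.96 percentage points at the main depth, -8.04 after thinning to the median (which also left out 1101 wild-type and 3878 enhancer-deleted cells) and -14.3 without thinning. The log2 ratio of shares of HSPC-like cells was 0.62 at resolution 2.0, 0.44 without the changed genes and 0.62 to 0.73 with a library left out, each without a call. It was -1.11 to -1.06 for basophil/mast-like and -4.08 to -3.17 for neutrophil-like cells with a library left out. Basophil/mast-like cells were at -3.90 at resolution 2.0, -7.78 without the changed genes (0 enhancer-deleted cells) and -0.84 by the highest marker score. Neutrophil-like cells were at -2.80 after thinning and -1.76 by the highest marker score. Erythroid-like cells were at -0.16 by the highest marker score, which gives every cell a class. Monocyte-like cells gained a call after thinning (1.12) and by the highest marker score (0.77). Of 15 lists, 8 passed camera, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 4 passed fry. No basophil/mast-like class formed at resolution 0.5 or after thinning, so it has no value there.

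The doublet caller marked 0.0329% to 0.313% of cells per library and did not work, so the dependence on doublets stayed untested. Without the marked cells every class kept its direction and side of the threshold (HSPC-like cells 0.68, adjusted p = 0.0196; neutrophil-like cells -3.58, adjusted p = 0.00899). No paired analysis was possible because the deposited cells carry library letters that are not tied to the replicate numbers, so the replicate block was not run. This holds for pairs by replicate number only. The term for Xist groups F with A and I with B, and thus acts as a block over all cells. With it 481 genes passed, against 321 without it. No such term was fitted to class shares or within classes. At these depths and with 2 libraries per genotype, 94% of simulated 1.5-fold and 32% of smaller simulated changes were recovered over all cells, and 76% to 90% of 1.5-fold changes within classes.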

Other observations

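The counts of list genes within classes, and the genes named with them, were chosen after their values had been seen, and the test of genes near Gata2 before. These counts are single-gene edgeR results, with no test of the list itself. The stem cell genes that rose over all cells were not shown to do so within HSPC-like cells, where 0 of 8 passed edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 past the DESeq2 Wald test, median log2 fold change -0.05). In these cells 3 of 5 basophil/mast genes fell (4 adjusted over the list alone), namely Cpa3, Hdc (12.4 to 0.956 CPM) and Lmo4 (80.5 to 38.8). Of 25 transcription regulators 4 fell (9 adjusted over the list alone), namely Gata2, Gata1 (9.08 to 0.470), Ikzf2 (83.1 to 44.8) and Myb (138 to 106).

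In basophil/mast-like cells 6 of 24 regulators fell and Irf8 and Ikzf1 rose (12 adjusted over the list alone). The megakaryocyte gene Gp9 fell from 6.34 to 0.679 CPM and Prg3 of eosinophils from 18.4 to 0.339. This class held 1272300 and 1473530 UMIs in libraries A and B, so both enhancer-deleted values rest on very few UMIs. In monocyte-like cells 6 of 13 neutrophil genes fell (12 adjusted over the list alone), namely Fcnb, S100a8, Elane (2965 to 1122), Cebpe, Ctsg and Ms4a3. Of 12 monocyte/macrophage genes 3 rose there (6 adjusted over the list alone), namely Cx3cr1, Ccr2 (64.8 to 111) and Csf1r (60.9 to 93.7). The cytokine receptor Flt3 also rose there, from 2.93 to 9.84. The cluster with the markers Elane, Ctsg and Ms4a3 held 69.1% of this class in the wild type and 32.5% in the enhancer-deleted libraries. The changes in monocyte-like cells were not separated from that shift.

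Sequence carried along with the deletion on chromosome 6 could change genes near Gata2. Within 10 megabases 2 of 40 measured genes (5.00%) passed edgeR over all cells, Spr and Xpc, against 8.997% of the other placed genes. The one-sided Fisher exact p was 0.886, so the changed genes did not gather there.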
